A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

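RNA of budding yeast was measured on 5 single-colour Affymetrix expression arrays, 2 from the wild type and 3 from a strain without VTS1. Per the labels, the deletion was made in BMA64, a laboratory strain of the W303 type, and total RNA was labelled with biotin. MAS5, a program that turns the probes of each probe set into 1 signal, is named in the submitters' processing notes, and its version and scaling target are not given in the sources used here. The deposited values are signal intensity values on a linear scale with 1 decimal. They had been scaled per array before deposit, as the values show: the mean signal after leaving out 2% of the probe sets at each end lay between 2502.47 and 2502.68 on the 5 arrays. They were therefore used without further scaling. Scaling of this kind assumes an equal total signal per array, so a change in the total amount of mRNA per cell would not be seen. The labels do not say whether the arrays came from separate cultures, and p-values measure only the spread between these arrays, which may be technical.

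The table held 9335 probe sets. The 60 control probe sets were left out of the main test, which left 9275. Gene names came from the platform annotation and were compared with the reference gene table by gene identifier: 6504 probe sets had 1 gene, 328 had several and 2443 had none, and all 6504 identifiers were found in the reference. No gene was named from a probe set with several genes. Signals under 50.1, which is the trimmed mean divided by 50, were raised to that floor, and log2 was taken. The 6294 probe sets with a mean signal over all 5 arrays of at least 250.3, the trimmed mean divided by 10, were tested. Of these, 5384 had 1 gene (4950 genes in all), 264 had several and 646 had none.

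Deletion and wild type were compared with limma version 3.58.1 in R version 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean signal), with group as the only term. The fit had 3 residual degrees of freedom and a prior of 9.02. P-values were two-sided and adjusted by the method of Benjamini and Hochberg over all probe sets tested, with a threshold of 0.05. Log2 changes are deletion minus wild type and have the standard error of the fit. Signal means have their SD. An array's background level was the 95th percentile of 28 control probe sets with no target in unspiked yeast RNA. Where all arrays of a group lay at or below that level, the fold is given as "at least": the mean log2 signal of the brighter group against the mean, over the arrays of the dimmer group, of the log2 of the higher of the background level and the signal itself. The number of arrays limits the precision of every value.

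Gene lists numbering 47 were written from textbook knowledge before the data were examined, as were the tests of the main comparison, the main settings, all alternatives but 1, and the rule for the genes named. That rule took VTS1 and its neighbours HAP5 and PDE2, all auxotrophic marker genes listed, YIR016W, the 10 single-gene probe sets with the largest log2 change in each direction among those past the threshold whose groups did not overlap, and up to 4 genes with the smallest p from each list that had a call or at least 2 called genes. The genes DBF2, DIC1, RPS14B, STE2 and STE3 and the unnamed probe set 3982_at fall outside that rule and were chosen after their values were seen. IZH2, IZH4, ZAP1 and ZRC1 also fall outside it and belong to a test written before their values were seen. A list used 1 probe set per gene, the one with the highest mean over the 5 arrays. The 45 lists with at least 4 measured genes were tested with camera of limma, which asks whether the genes of a list rank higher or lower than the other genes, at a preset inter-gene correlation of 0.01, with adjustment over the 45 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run as alternatives. With an estimated correlation, camera takes its p-values from the 3 residual degrees of freedom instead of the number of genes. 6 list entries had no gene in the reference under the name written.

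The procedure was tested on simulated data for this comparison: 20 simulations of 6294 probe sets on 5 arrays, with 200 probe sets changed. At 1.5-fold, 28.5% of the changed probe sets were called. The share was 74.2% at 2-fold and 97.8% at 4-fold, and 4.15% of all calls were false on average. Each simulated probe set varied independently, with normal noise and a variance drawn from the fitted prior. Genes that move together, trends with probe set number and differences between cultures were not simulated. The false share therefore need not hold for the calls made here. The alternatives were other normalizations, floors, filters, variance models and array weights, a test against a 1.2-fold minimum, plain probe sets alone, each array left out in turn, and a block on the replicate number. A planned search of transcripts for the hairpin that Vts1 binds was not run, since no transcript sequences were used here.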

Results

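The transcripts of yeast cells without VTS1 were compared with those of the wild type on 5 arrays, 2 from the wild type and 3 from the deletion strain. Vts1 is an RNA-binding protein with a SAM domain of the Smaug type, which recognises short hairpins in mRNA and promotes the decay of the mRNAs that carry them. The comparison asks which transcripts differ in level when the protein is missing. Between 74.2% and 83.0% of the probe sets lay above the background level on each array. Over all probe sets tested, log2 signals correlated at r = 0.981 to 0.990 between arrays of 1 group and at 0.960 to 0.969 between arrays of different groups (across genes, which are not independent replicates). No pair of arrays held identical values.

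VTS1 (YOR359W) itself was bright in the wild type and at background in the deletion strain, as the labels state. Its signal was 4952.3 and 5079.9 on the wild type arrays and 19, 17.8 and 55 on the deletion arrays, at least 33.4-fold lower (adjusted p = 8.46e-09). Its chromosomal neighbours had no call: HAP5, a subunit of the CCAAT-binding factor, had a log2 change of 0.15 ± 0.19 (SE, n = 3 against 2, adjusted p = 0.702) and PDE2, a cyclic AMP phosphodiesterase, one of 0.07 ± 0.13 (adjusted p = 0.816). YIR016W, listed beforehand as a known or proposed Vts1 target, rose from a signal of 2479 ± 371 (SD, n = 2) to 4598 ± 343 (SD, n = 3). Its log2 change was 0.90 ± 0.14 (adjusted p = 0.00147), and all 3 deletion arrays lay above both wild type arrays. Without the filter on dim probe sets this call was lost.

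None of the auxotrophic marker genes had a call. The adjusted p was 0.520 for ADE2, 0.245 for CAN1, 0.903 for HIS3 and 0.535 for TRP1, with log2 changes of 0.14 ± 0.12, -0.38 ± 0.18, 0.04 ± 0.13 and 0.29 ± 0.24. LEU2 and URA3 were too dim to be tested, with mean signals (the brightest of 3 probe sets for LEU2) of 81.7 and 12.9 in the wild type and 113.1 and 10.1 in the deletion strain. The a-cell gene STE2 had a signal of 4941 ± 79.0 in the wild type and 5076 ± 346 in the deletion strain, while the alpha-cell gene STE3 lay at 194.0 ± 32.0 and 190.9 ± 66.8.

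Zinc-responsive genes, ZPS1 and ZRT1 above all, were among the 10 largest decreases of single-gene probe sets. ZPS1, a cell-surface protein made in zinc shortage, fell from a signal of 60644 ± 7544 to 1436 ± 119, a log2 change of -5.40 ± 0.13 (adjusted p = 5.33e-11). ZRT1, the high-affinity zinc transporter, fell from 41849 ± 2938 to 1412 ± 271 (log2 change -4.91 ± 0.16, adjusted p = 1.02e-09). ADH4, an alcohol dehydrogenase induced without zinc, had a log2 change of -2.11 ± 0.13 (adjusted p = 8.17e-07), and ZRT3, which exports zinc from the vacuole, fell from 9221 ± 1450 to 4007 ± 378 (adjusted p = 0.00017). Of 17 measured genes of the zinc and copper list, 8 fell (8 adjusted over the list alone) and none rose (1 adjusted over the list alone). The others that fell were ZAP1, the zinc-sensing activator of these genes, ZRC1, IZH2 and IZH4. Their log2 changes were -0.93 ± 0.25, -0.57 ± 0.14, -0.77 ± 0.12 and -1.04 ± 0.18 (adjusted p = 0.0433, 0.0302, 0.00182 and 0.0029). The list ranked below other genes (camera adjusted p = 1.22e-05; adjusted p = 0.289 with an estimated correlation). Without the filter on dim probe sets 3 of its genes fell and 1 rose, and the call of ZRT3 was lost. The 8 genes that fell became 6 without deletion replicate 1, deletion replicate 2 or a variance trend. Fewer than 8 also fell with any other array left out. The probe sets of ZRT1 disagreed: 3 of the 4 fell, with log2 changes of -4.91, -5.15 and -3.64, and the dimmest rose by 1.12 ± 0.22, from 327.0 to 716.5 (adjusted p = 0.00813).

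Most genes of the general stress list were higher in the deletion strain. HSP12, a small membrane-associated stress protein, rose from a signal of 6277 ± 845 to 62309 ± 1642, a log2 change of 3.32 ± 0.12 (adjusted p = 4.19e-09). SOL4, of the pentose phosphate pathway, rose by 3.90 ± 0.20, GPH1, glycogen phosphorylase, by 3.77 ± 0.33, and GLC3, the glycogen branching enzyme, which is not in the list, by 3.40 ± 0.20 (adjusted p = 1.17e-07, 2.30e-05 and 6.15e-07). HXK1, a hexokinase repressed by glucose, rose by 2.81 ± 0.13, GAD1, glutamate decarboxylase, by 2.82 ± 0.22, and the secreted glycoprotein YGP1 by 2.80 ± 0.12 (adjusted p = 4.79e-08, 7.28e-06 and 1.82e-08). XBP1, a stress-induced repressor, and CTT1, cytosolic catalase, were at background in the wild type and at least 5.13-fold and 4.70-fold higher in the deletion strain (adjusted p = 7.43e-05 and 0.00136). Of 49 measured genes of the list of Msn2 and Msn4 type stress genes, 37 rose and 1, the small heat shock gene HSP26, fell, with a median log2 change of 1.21 (the same value with the 2 genes at their bounds). Adjusted over the list alone, 41 rose and 1 fell. The list ranked above other genes (camera adjusted p = 1.02e-37; adjusted p = 0.315 with an estimated correlation). Without the filter on dim probe sets 13 of its genes rose. The calls of GPH1, GAD1 and HSP26, unlike those of HSP12, SOL4, GLC3, HXK1, YGP1 and XBP1, were then lost, as was that of CTT1. Beside these changes, 1 of 5 control probe sets for 18S ribosomal RNA fell from 3303 to 1054 (adjusted p = 0.00863 over the 60 controls), and the ratio of the 3' to the 5' probe set of actin was 1.34 and 1.17 in the wild type against 1.51, 1.35 and 1.25 in the deletion strain. The same ratio was 3.39 and 2.42 against 3.02, 3.64 and 5.32 for SRB4, and 2.70 and 2.82 against 2.60, 2.79 and 2.37 for TBP.

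**Figure D1:**
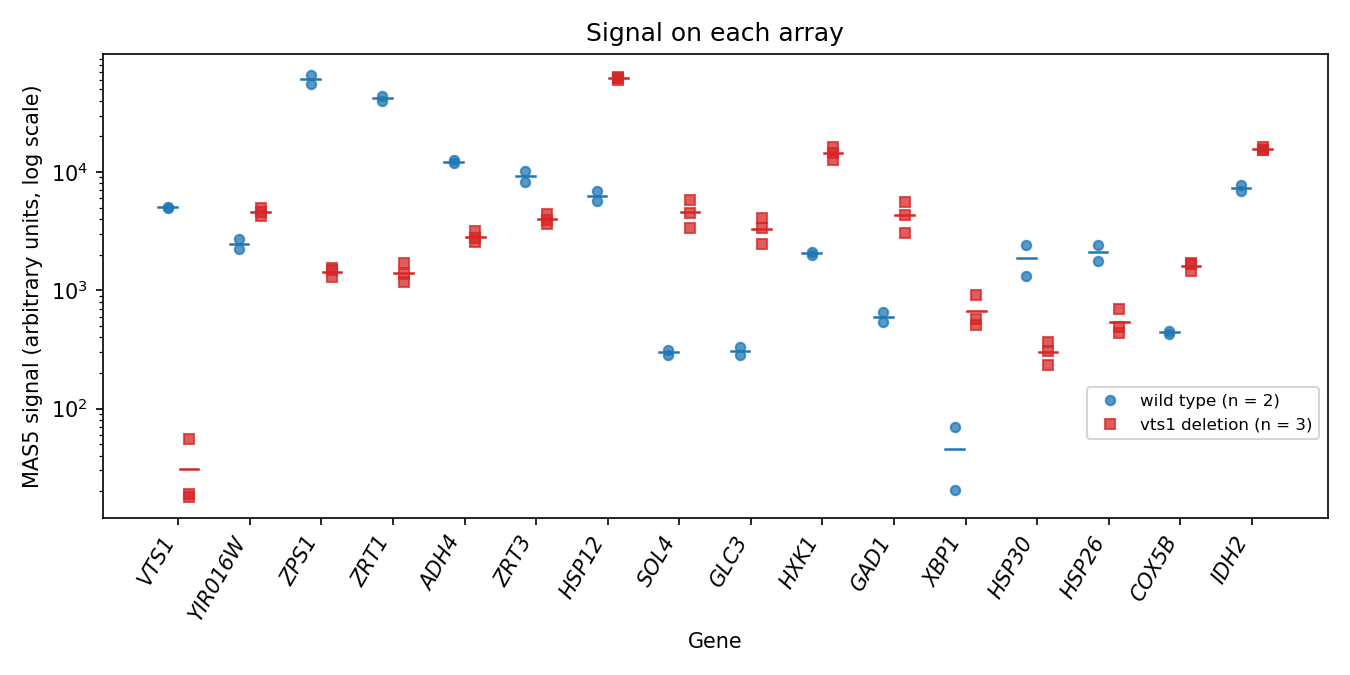
MAS5 signal (arbitrary units, log axis) of 16 genes on each of the 2 wild type arrays (circles) and 3 vts1 deletion arrays (squares), with short lines at the group means; ZRT1 is shown by the brightest of its probe sets. VTS1 lies at 4952.3 and 5079.9 in the wild type and at 55 or less in the deletion strain, and HSP12 moves from a mean of 6277 to 62309.

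The heat shock chaperone list did not follow the general stress list, with which it shares HSP26 and some other genes. Of 31 measured, 8 fell (8 adjusted over the list alone) and 1 rose (2 adjusted over the list alone). The log2 change was -2.58 ± 0.28 for HSP30, a plasma membrane heat shock protein, -1.97 ± 0.22 for HSP26 and -1.88 ± 0.22 for BTN2, a protein-sorting factor of stressed cells (adjusted p = 9.99e-05, 0.000136 and 0.000192), while the polyubiquitin gene UBI4 rose by 0.82 ± 0.14 (adjusted p = 0.00259). The list ranked below other genes (camera adjusted p = 0.00261; adjusted p = 0.351 with an estimated correlation), a call lost with a stricter filter on dim probe sets. The number that fell was 5 without wild type replicate 1, wild type replicate 2, deletion replicate 2 or deletion replicate 3, or without a variance trend, and 1 without the filter, where HSP30, HSP26, BTN2 and UBI4 lost their calls. YOL014W, of unknown function, fell by 2.22 ± 0.25 (adjusted p = 0.000133), a call also lost without the filter.

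Part of the respiratory genes rose. Of 41 measured genes of oxidative phosphorylation, 17 rose (21 adjusted over the list alone) and none fell, among them COX5B and COX4, subunits of cytochrome c oxidase, by 1.85 ± 0.17 and 1.01 ± 0.14 (adjusted p = 2.73e-05 and 0.000703). Of 22 genes of the tricarboxylic acid cycle, 10 rose and 1, the mitochondrial dicarboxylate carrier gene DIC1, fell (13 and 1 adjusted over the list alone). IDH2, a subunit of isocitrate dehydrogenase, rose by 1.10 ± 0.11, and ACO1, aconitase, by 1.15 ± 0.13 (adjusted p = 8.37e-05 and 0.00016). Both lists ranked above other genes (camera adjusted p = 5.79e-15 and 2.42e-08; adjusted p = 0.289 for each with an estimated correlation). The 17 oxidative phosphorylation genes became 9 without wild type replicate 2, 9 without deletion replicate 2, 7 without deletion replicate 3, 7 without a variance trend and 2 without the filter on dim probe sets. The 10 genes of the tricarboxylic acid cycle became 6 without deletion replicate 2, 5 without a variance trend and 2 without the filter. The call of DIC1 was lost, among others, without wild type replicate 2, deletion replicate 3, a variance trend or the filter. HXT7 and HXT6, near-identical high-affinity hexose transporters that their probe sets may not separate, rose by 1.19 ± 0.12 and 1.11 ± 0.13, HXT4 by 1.51 ± 0.16 (adjusted p = 5.82e-05, 0.000214 and 8.58e-05). In the hexose transport and glucose repression list, 4 of 20 rose and 1 fell (4 and 1 adjusted over the list alone), and the list as a whole had no call (camera adjusted p = 0.461).

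Genes of metal and nitrogen uptake moved in smaller groups. Of 27 iron regulon genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone), with SIT1, a siderophore transporter, higher by 1.15 ± 0.17 and FTR1, the iron permease, by 0.75 ± 0.12 (adjusted p = 0.000942 and 0.00174). FET4, a low-affinity transporter of iron and zinc, fell by 1.73 ± 0.20 (adjusted p = 0.000155). The list ranked above other genes (camera adjusted p = 0.00668; adjusted p = 0.351 with an estimated correlation), and 0 of its genes had a call without the filter on dim probe sets. Without deletion replicate 2, deletion replicate 3 or a variance trend, 5 of its genes rose and 1 fell. Fewer also rose with any other array left out. Of 25 genes under nitrogen catabolite repression, 5 rose (6 adjusted over the list alone) and none fell, among them the proline permease gene PUT4, by 1.63 ± 0.22, and the vacuolar protease gene PEP4, by 0.94 ± 0.12 (adjusted p = 0.0006 and 0.000402). This list also ranked above other genes (camera adjusted p = 0.00399; adjusted p = 0.45 with an estimated correlation). The number that rose was 3 without wild type replicate 2 and 2 without the filter. Of 18 amino acid permease genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone), with DIP5, which carries acidic amino acids, higher by 1.48 ± 0.15 (adjusted p = 6.02e-05). The permease list ranked higher (camera adjusted p = 0.0494; adjusted p = 0.626 with an estimated correlation), a call kept under 10 of 17 alternatives and lost, among others, without wild type replicate 2 or deletion replicate 3. Without wild type replicate 1, 5 rose and 0 fell, and the decrease, that of TAT1, also lost its call without wild type replicate 2, deletion replicate 2 or deletion replicate 3.

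Growth-related lists ranked lower, with few genes called. Of 79 ribosome biogenesis genes, 5 fell (0 adjusted over the list alone), with a median log2 change of -0.24 (camera adjusted p = 1.51e-08; adjusted p = 0.175 with an estimated correlation). NOP16, a ribosome assembly factor, fell by 0.49 ± 0.12 (adjusted p = 0.0281). Of 27 subunits and factors of RNA polymerases I and III, 3 fell (3 adjusted over the list alone), with a log2 change of -0.98 ± 0.19 for RRN3, an initiation factor (adjusted p = 0.00764), and the list had a camera adjusted p of 6.36e-05 (adjusted p = 0.351 with an estimated correlation). Of 32 translation factors, 2 fell (5 adjusted over the list alone): ANB1, the form of eIF5A made without oxygen, with a log2 change of -1.48 ± 0.19, and TIF5, with -0.52 ± 0.12 (adjusted p = 0.000314 and 0.0211; camera adjusted p = 0.00261; adjusted p = 0.302 with an estimated correlation). With arrays left out in turn, between 0 (without deletion replicate 3) and 4 ribosome biogenesis genes fell (without wild type replicate 1, 4 fell and 2 rose), and the number for the polymerases was 1 without wild type replicate 2 or deletion replicate 2. The call of NOP16 was lost without wild type replicate 2, deletion replicate 2 or deletion replicate 3, and that of TIF5 without any 1 array but deletion replicate 1. The cytosolic ribosomal protein genes, 81 of them measured, had a median of -0.11. Of these 1, RPS14B, fell (0 adjusted over the list alone), and the list as a whole had no call (camera adjusted p = 0.0502; adjusted p = 0.783 with an estimated correlation).

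Pheromone response genes ranked lower: of 19, 3 fell (7 adjusted over the list alone), namely AGA1, an agglutinin subunit, FUS1, a cell fusion protein, and SST2, a regulator of the pheromone signal. Their log2 changes were -1.04 ± 0.12, -1.29 ± 0.26 and -0.95 ± 0.19 (adjusted p = 0.0002, 0.00816 and 0.00912; camera adjusted p = 0.00247; adjusted p = 0.289 with an estimated correlation). Of 16 multidrug resistance genes, 3 fell (4 adjusted over the list alone), among them the drug pump gene PDR5, with a log2 change of -0.62 ± 0.14 (adjusted p = 0.0204) at its brightest probe set and called decreases of -1.05 to -1.46 at 4 of its 5 others (list camera adjusted p = 0.00668; adjusted p = 0.614 with an estimated correlation). Of 27 ergosterol genes, 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0405; adjusted p = 0.614 with an estimated correlation), and of 29 methionine and sulfur genes 2 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.0494; adjusted p = 0.433 with an estimated correlation). In the list of anaerobic and cell wall mannoprotein genes, which had no call as a whole (camera adjusted p = 0.129), 5 of 19 fell and 2 rose (7 and 3 adjusted over the list alone), with a log2 change of -1.85 ± 0.12 for the mannoprotein gene TIR1 (adjusted p = 1.50e-06). The 2 that rose, COX5B among them, were also counted above with oxidative phosphorylation. In the purine and one-carbon list, with no call either (camera adjusted p = 0.643), 3 of 27 rose and 1 fell (3 and 4 adjusted over the list alone). IMD2, of guanine nucleotide synthesis, had a log2 change of -0.78 ± 0.12 (adjusted p = 0.00097), while GCV1, GCV2 and GCV3 of the glycine cleavage system rose by 1.37 ± 0.14, 1.26 ± 0.15 and 0.60 ± 0.13 (adjusted p = 5.86e-05, 0.000171 and 0.0126). Leaving out wild type replicate 1 ended the calls of SST2, PDR5 (brightest probe set), GCV3 and the multidrug and methionine lists, and leaving out wild type replicate 2 those of FUS1, PDR5 and the ergosterol list. Leaving out deletion replicate 2 ended those of PDR5, GCV3 and the ergosterol and methionine lists, and leaving out deletion replicate 3 those of SST2 and GCV3. The number of multidrug genes that fell was 1 without wild type replicate 1 (where 1 rose), wild type replicate 2 or deletion replicate 2. Over 17 alternatives the ergosterol list kept its call in 12 and the methionine list in 11. Without deletion replicate 2, 1 methionine and sulfur gene fell and 0 rose.

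**Figure D2:**
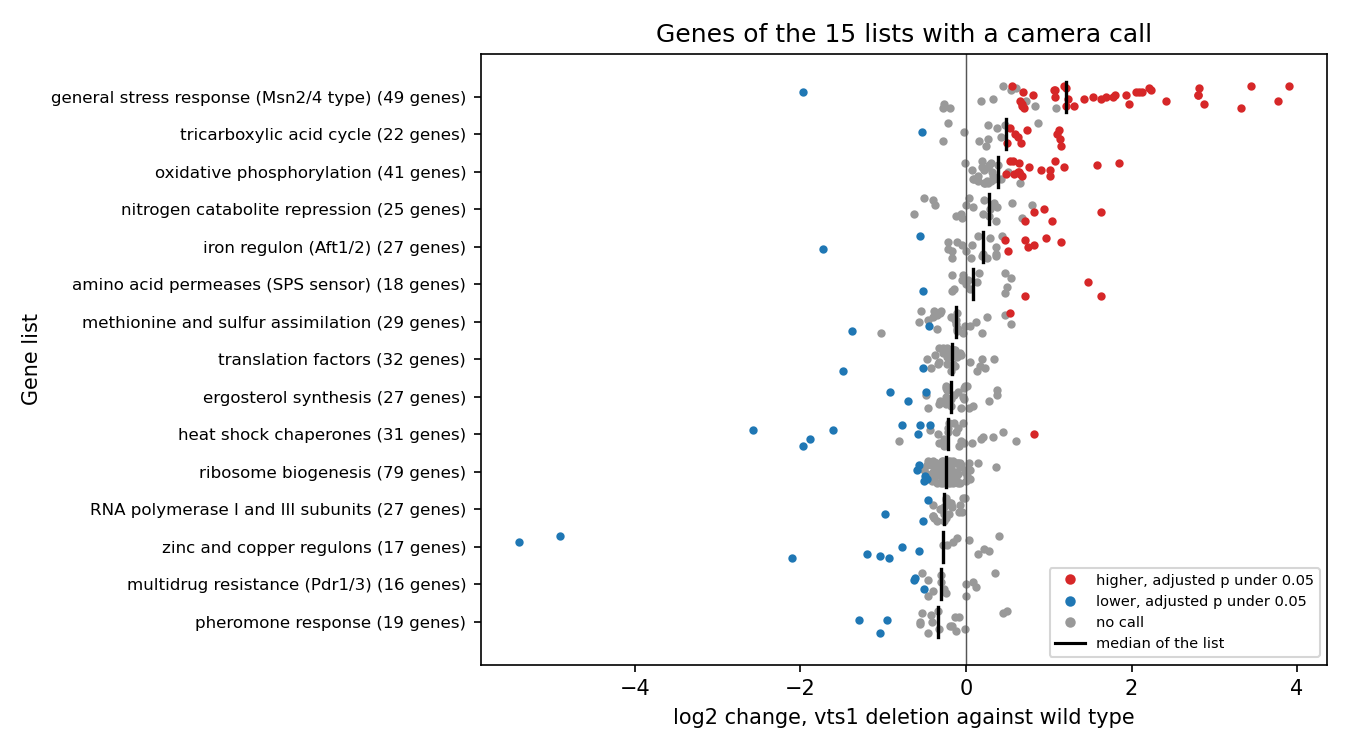
Log2 change (deletion against wild type, horizontal axis) of each measured gene in the 15 gene lists with a camera call. Each point is 1 gene, coloured by whether it rose or fell with an adjusted p under 0.05, and black lines are list medians. The stress list has a median of 1.21 and lies apart from the others.

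In all, 276 probe sets (251 genes) were higher and 192 (145 genes) lower in the deletion strain, 117 and 52 of them by more than 2-fold, out of 6294 tested. At an unadjusted p under 0.05 there were 648 and 696. In every one of the called probe sets all 3 deletion arrays lay on the same side of both wild type arrays. The calls rest on the same values, so this is not separate support. Over all probe sets tested, 1055 separated upward and 1368 downward, where chance gives 10% in each direction. Camera called 15 of 45 lists, 6 higher and 9 lower. With an estimated correlation, camera called 0 of 45, and fry called 9, of which 7 were among the 15. The 2 called by fry alone were the list of VTS1 and its neighbours, which holds the deleted gene, and the gluconeogenesis list. The numbers of higher and lower probe sets dropped to 54 and 51 without the filter on dim probe sets, where 29 of 93 named probe sets besides VTS1 kept their call, and to 181 and 95 without deletion replicate 2 or 175 and 112 without deletion replicate 3. The number of lower probe sets was 112 without wild type replicate 1, 121 without wild type replicate 2 and 106 without a variance trend.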

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

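Removing each array's trend with probe set number was chosen after seeing the data; the other alternatives were set beforehand. VTS1 stayed lower and past the threshold under all 18 alternatives. The 276 higher and 192 lower probe sets became 54 and 51 without the filter on dim probe sets, of which 50 and 37 were among the main ones; 9275 instead of 6294 probe sets were then tested, and the cause was not otherwise tested. Against a 1.2-fold minimum, a stricter question, 146 and 54 were left. Without a variance trend 106 were lower, and the cause was not tested. Leaving out each array in turn, which leaves fewer samples, gave 175 to 318 higher and 95 to 165 lower; where 1 wild type array was left, it is assumed to vary like the deletion arrays. With a replicate block on the arrays numbered 1 and 2 alone, which leaves 4 arrays and 1 residual degree of freedom, 144 were higher and 74 lower. The arrays share only a number: the difference between the wild type arrays and that between deletion replicates 1 and 2 correlated at r = -0.08 across genes. Camera called 15 lists, and 0 with an estimated correlation. The estimate was 0.51 for the stress list and 0.14 for oxidative phosphorylation, above the preset 0.01. For ribosome biogenesis it was -0.006, and the unadjusted camera p still rose from 1.01e-09 to 0.00388. A higher correlation was thus not the only source of the loss. With an estimate, camera uses the 3 residual degrees of freedom, and with a preset value the far larger number of genes. How much of the loss in the other lists came from this was not tested. The camera calls rest on the preset value and on the degrees of freedom that go with it. Fry, which asks another question, called 9 lists, 7 of them among those 15. With the trend removed, 12 of the 15 lists kept their call. Of 93 named probe sets with a call besides VTS1, 29 kept it without the filter, 65 without a variance trend, 58 against 1.2-fold and 61 with the replicate block, and 89 with the trend removed; none reversed. HIS3 and TRP1, which had no call, changed sign, and the cause was not tested. The log2 change of HIS3 was -0.034 with array weights and -0.0432 to 0.118 with arrays left out, and the log2 change of TRP1 was -0.157 to 0.737 with arrays left out. Probe sets near background, 98.0 to 166.7 on these arrays, give only bounds. The planned counts of genes with a Vts1 hairpin were not run.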

Other observations

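The tests of cross-hybridization, RNA degradation and a restored marker gene, the values of single array pairs for the chromosome and the removal of the trend with probe set number were chosen only after the results they concern had been seen.

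Other lists had no call as a whole. Of 39 measured genes of cell wall integrity and chitin, 5 rose and 1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.461), among them the mannoprotein gene CWP1, with a log2 change of 0.89 ± 0.13 (adjusted p = 0.000803). PST1, ASH1 and CRH1, which also rose, lost their calls without deletion replicate 3, and these genes and CWP1 lost them without the filter. Of 27 genes of oxidative stress and thiol redox, 5 rose and 1, the sulfiredoxin gene SRX1, fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.19), with the mitochondrial superoxide dismutase gene SOD2 higher by 0.65 ± 0.13 (adjusted p = 0.00686). The call of SRX1, with a log2 change of -0.88 ± 0.22, was lost, among others, without wild type replicate 1, deletion replicate 2, a variance trend or the filter. Of 14 genes listed with the deadenylase complexes, through which Smaug-type proteins act on mRNA, 1 fell (1 adjusted over the list alone). It was the protein kinase gene DBF2, with a log2 change of -0.67 ± 0.17 (adjusted p = 0.0366), and the other 13 had no call. Of 21 genes of decapping and decay from the 5' end 0 had a call (camera adjusted p = 0.614 and 0.806 for the 2 lists). Genes of mitochondrial ribosomes, 66 measured, had 0 calls (camera adjusted p = 0.84). The polyamine exporter gene TPO2 rose by 3.11 ± 0.16 (adjusted p = 1.13e-07).

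For the fall of the zinc genes, the median log2 change of ZRT1, ZPS1 and ADH4 was still -4.87 after quantile normalization. The signal distributions of the arrays already lay close together, with upper quartiles of 2136.6 to 2349.7, so this test could move the change little. It shows only that differing signal distributions did not make the fall of these genes. The iron regulon without FET4 and COT1 had a median of 0.20, which argues against a decrease shared by the iron genes. That test looked only for a decrease and only at iron, so a disturbance of other metals, or one that raises iron genes, stays open. The 4 ZRT1 probe sets disagreed, the dimmest at 1.12 while the other 3 fell, as cross-hybridization of single probe sets would give. By the bounds first written, on ZRT1 alone, that explanation was met. A rise of the dimmest probe set does not account for the fall of the others, so this outcome does not decide the source of the decreases. A second test, with bounds written after that outcome and with the decreases already known, counted 8 genes of the list lower with plain probe sets alone, but 1 of its 17 genes then had another probe set, so it nearly repeats the main count and leaves cross-hybridization open. A difference in zinc supply between the cultures stays open as a candidate explanation, with 5 of 6 further zinc genes lower in a test fixed before their values were seen, and an effect of the deletion itself on zinc balance, untested, would give the same values.

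For the rise of the stress genes, a single deviating array is argued against, since at least 31 of the main 37 genes' number rose with any 1 array left out. RNA degradation stays open: the 3' to 5' log2 ratio differed between the groups by 0.13 ± 0.13 (SE) for ACT1, 0.44 ± 0.34 for SRB4 and -0.10 ± 0.07 for TBP, so the 0.5 set as a bound is not excluded for SRB4, and 1 of 5 18S control probe sets fell. Denser or slower-growing cultures could give this pattern, and the median of the ribosome biogenesis genes, -0.24, lay between the values set beforehand for and against it, so growth state and deletion cannot be told apart here. An effect of Vts1 on these mRNAs was not tested.

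An unnamed probe set, 3982_at, had signals of 8.2 and 10.5 in the wild type and 67408, 50105 and 50036 in the deletion strain, at least 440.1-fold higher (adjusted p = 5.43e-13). It was the only 1 of all probe sets that went from background to above the trimmed mean, as a sequence brought in with the deletion construct could give, and that stays open as a hypothesis. Whether a native marker gene was restored with the deletion cannot be told apart: the largest log2 change of the measured marker genes was 0.29, but these genes were already bright in the wild type, so a restored allele need not raise them. LEU2 and URA3 stayed dim, with mean signals of 113.1 and 10.1 in the deletion strain, and no array here shows whether their probe sets detect a native copy.

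Gain or loss of a chromosome was tested as a source of the many changes. The largest chromosome median, of chromosome VI, was 0.19, between the values set beforehand for and against it, and over the 6 pairs of a deletion and a wild type array it lay between 0.03 and 0.22, below the 0.3 set for a gain in each. Probe set numbers mostly run in blocks by chromosome, so a trend with number and differences between chromosomes cannot be told apart. The median log2 change was 0.10 for the probe sets numbered 4715 to 5568 and -0.13 for those numbered 9736 to 10567. This trend lay mainly on wild type replicate 2 and deletion replicate 1. Removing that trend can also remove differences between chromosomes, so it does not decide between them. With the trend removed, the median of chromosome VI was 0.13 and the next in size was 0.04. Of the 276 higher and 192 lower calls, 271 and 161 were then kept.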
